A study of Drosophila melanogaster with 3 samples.

How the data were processed

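RNA from the midgut of EcR mutant Drosophila melanogaster was compared with a pooled wild-type midgut reference on 3 arrays with 2 channels each. Per the labels, total RNA was amplified by in vitro transcription before labelling, the mutant sample was read at 635 nm (Cy5) and the reference at 532 nm (Cy3), and the 3 mutant samples were independent. All arrays had 1 dye orientation, so a dye effect stays in every mean. The scanner software, the background correction, the spot filter and the reason for empty values are not given in the sources used here.

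The deposited values are 1 log2 ratio per probe and array for 20000 probes. The scale was settled from the values themselves. For values under 1.5, 2 to the power of the value plus 1 constant per array was a whole multiple of 0.001 for 100% of values (tolerance 0.02 of a step), with constants of 0.0649 for replicate 3, 0.0574 for replicate 4 and 0.2082 for replicate 6. For natural logs, log10 and the inverse ratios this held for 3.71% to 5.83% of values. The values checked were therefore logs of ratios in steps of 0.001, with 1 constant subtracted per array. A correction that depends on intensity was not made after that rounding, but one made before it would leave the same steps. The deposited medians were 0.0475, 0.0483 and 0.0858 for replicates 3, 4 and 6, and the SDs over probes were 0.473, 0.462 and 0.579. The file does not state which channel is the numerator, and mutant over reference was taken as the likely direction from the channel order in the labels. No intensities, backgrounds or spot flags were used here, so a filter on dim or saturated spots could not be applied and signal over background is unknown.

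A value was present on all arrays for 13921 probes, on replicate 3 alone for 4975 and on no array for 893. Of the probes on replicate 3 alone, 4953 had no gene symbol. Probe names came from the platform annotation, in which 10828 probes had 1 gene symbol, 227 had several and 8945 had none. By gene ID 10824 of the 10828 were matched to the gene table of the Release 6 plus ISO1 MT assembly, and 0 symbols had to be updated. Probes with several symbols or none were kept as unnamed features. Each array was centred on its median, probes of 1 gene were averaged, and features with a value on all arrays were tested. Of the 9756 genes, 769 had more than 1 probe, with a median range between probes of 0.108 (log2), and 9 of them had probes past the threshold in opposite directions.

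The mean log2 ratio of each feature was tested against 0, two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without trend and not robust, with Benjamini-Hochberg adjustment over all 13026 features and a threshold of 0.05. The test had 6.89 degrees of freedom per feature, prior included. The reference counts as 1 control sample, so its own spread does not enter. Gene lists were tested with camera at its preset correlation of 0.01 where at least 5 members were tested, with adjustment over 28 lists, and again with an estimated correlation and with fry. The 29 lists, the test and the rule for naming genes were fixed before the data were examined. The rule named EcR, the 10 highest and 10 lowest named genes past the threshold with the same sign on all arrays, and up to 4 members per list past the threshold with the largest absolute ratio. Some lists were built from symbol patterns. The P450 pattern also took in 2 cyclophilins, the cytosolic ribosomal list holds bonsai, which encodes a mitochondrial ribosomal protein, and an entry of the mucin list resolved to Sgs1, a salivary glue gene.

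The alternatives were values as deposited, scaling to the same spread, quantile normalization, features on at least 2 arrays, each probe on its own, robust eBayes, a plain one-sample test, leaving out each replicate, an adjusted p under 0.01 and a change of at least 1.5-fold. Lists were also tested without genes that more than 1 list holds. Centring on probes with a value on all arrays and on chemosensory receptor probes (Or, Gr and Ir genes) were added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

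The procedure was tested on simulated data, with 13026 features drawn with the SD of each feature as moderated by eBayes and 200 of them changed. It recovered 100% of changes at each of the log2 sizes 0.5, 1 and 2. There were 23 false calls, which were 10.3% of the calls, above the nominal rate. In the data 4824 features were called, far more than were changed here, so these shares may not carry over to them. A proteasome list shifted by 1 was found with the preset correlation (adjusted p = 5.22e-21) and missed with an estimated one (adjusted p = 0.214), and 0 of 27 unshifted lists were called. Features were drawn independently of each other, so this says nothing about false calls of lists whose genes are correlated. For the digestive proteases, for example, the correlation estimated from the arrays was 0.587.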

Results

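Gene expression was measured in the larval midgut of Drosophila melanogaster mutants for EcR, which encodes the ecdysone receptor, the nuclear receptor that binds the steroid hormone ecdysone and starts molting and metamorphosis. The mutants lacked the function of all EcR isoforms, were carried through earlier larval life by a heat shock inducible EcR transgene, and were collected at stage 2a, the stage late in the last larval instar at which they arrest. RNA of the mutant midgut was hybridised on 3 arrays against 1 common reference, a pool of wild-type Canton S midgut RNA from various stages. The labels describe the 3 mutant samples as independent, and they are called replicates 3, 4 and 6 here after their titles. The arrays held a value for 18991 probes in replicate 3, 14097 in replicate 4 and 14069 in replicate 6, and 13026 features (9756 named genes and 3270 unnamed probes) had a value on all of them. With 3 arrays their number limits the precision, and the median SD between arrays was 0.104 on the log2 scale. The log2 ratios correlated across features with r = 0.902 (rho = 0.758) between replicates 3 and 4, r = 0.939 (rho = 0.836) between replicates 3 and 6, and r = 0.897 (rho = 0.762) between replicates 4 and 6, where features are not independent replicates. The sign of the ratio was the same on all 3 arrays for 67.2% of features. Independent arrays with no change would give 25%, but these arrays share a reference and a dye orientation, which raise the share and the correlations without any effect of the genotype.

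The comparison asks which transcripts of the midgut differ when the ecdysone receptor is missing. Positive log2 ratios below mean a higher level in the mutant. This direction is likely rather than stated, because the labels put the mutant in channel 1 (Cy5, 635 nm) and the reference in channel 2 (Cy3, 532 nm) while the value table does not say which channel was divided by which. If the ratio were reference over mutant, every sign, rank and count of higher and lower below would turn. The reference is wild-type RNA of mixed stages, and no wild-type midgut of the mutant's stage was on these arrays. A ratio therefore holds both the genotype and the difference in stage and leaves out the spread of the wild type. The heat shock inducible transgene and any difference in heat shock or strain background also lie in every ratio. The EcR transcript itself came first. Its probe gave a log2 ratio of 1.49 ± 0.83 (SD, n = 3 arrays; adjusted p = 0.0044), with 1.72 on replicate 3, 0.57 on replicate 4 and 2.19 on replicate 6. Without replicate 3 the value was 1.38 and its adjusted p was 0.0571. The files do not say whether the probe also detects RNA of the transgene or of the mutant alleles, so it does not check the loss of EcR function.

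The largest changes in both directions included enzymes of digestion. In the likely direction, the 10 named genes with the highest ratios were led by Bace at 4.18 ± 0.47 (SD, n = 3; adjusted p = 6.84e-06), which encodes an aspartic protease, and Mal-A1, a maltase, at 3.79 ± 0.19 (adjusted p = 1.25e-06). They were followed by CG14219 at 3.78, CG14205 at 3.65, CG14204 at 3.59, CG5550 at 3.58, CG15043 at 3.52, CG10911 at 3.34, CG8093 at 3.32 and mag, a lipase, at 3.12. The 10 lowest named genes were led by CG15169 at -3.28 ± 0.42 (adjusted p = 1.04e-05), CG7997 at -3.26 ± 0.39 (adjusted p = 9.39e-06) and Cht8, a chitinase, at -3.10 ± 0.57 (adjusted p = 3.1e-05). Below the reference there were also LysX, a lysozyme, at -3.0, CG16758 at -2.86 over 4 probes, CG3829 at -2.64, Spn27A, a serpin, at -2.61, CG8112 at -2.6, CREG at -2.59 and Ctr1B, a copper transporter, at -2.54.

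In all, 4824 of the 13026 features passed the limma test at an adjusted p under 0.05, of which 1743 were higher and 3081 lower in the mutant, so that 63.9% of the calls were lower. With the direction turned, 3081 would be higher and 1743 lower. The split depends on where 0 is set. On the values as deposited 3038 were higher and 2729 lower (47.3% lower), and with the arrays centred on chemosensory receptor probes, a setting chosen after seeing the data, 961 were higher and 4197 lower (81.4% lower). A change of at least 1.5-fold was reached by 1772 features (535 higher, 1237 lower), a change of at least 2-fold by 793 (282 higher, 511 lower) and a change of at least 4-fold by 129 (74 higher, 55 lower). Without replicate 3 the count fell to 2787 (792 higher, 1995 lower). A plain one-sample test with each feature's own variance passed 4 features, with 4366 at an unadjusted p under 0.05.

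Both lists of digestive enzymes were higher in the mutant. Of 27 digestive proteases tested, 23 were higher, 1 was lower and 3 did not pass, with a median log2 ratio of 1.12 (camera adjusted p = 2.06e-11; adjusted p = 0.558 with an estimated correlation). Adjusted over the list alone, 24 were higher and 1 lower. The serine protease genes Jon25Biii at 2.73 ± 0.49, Jon65Aii at 2.17 ± 0.43, Ser6 at 1.62 ± 0.34 and lambdaTry, a trypsin, at 1.61 ± 0.78 had the largest values, and Jon66Cii at -0.46 was the member that was lower. That lower call was not made without replicate 3 or without replicate 4. Of 24 carbohydrases, lysozymes and lipases, 18 were higher, 2 were lower and 4 did not pass, with a median of 1.22 (camera adjusted p = 3.29e-09; adjusted p = 0.487 with an estimated correlation). Adjusted over the list alone, 20 were higher and 2 lower. Besides Mal-A1 and mag, the lipase gene Lip3 stood at 3.04 ± 0.63, while the lysozyme gene LysX at -3.0 ± 0.31 and Mal-B2 at -0.29 were the members that were lower.

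**Figure D1:**
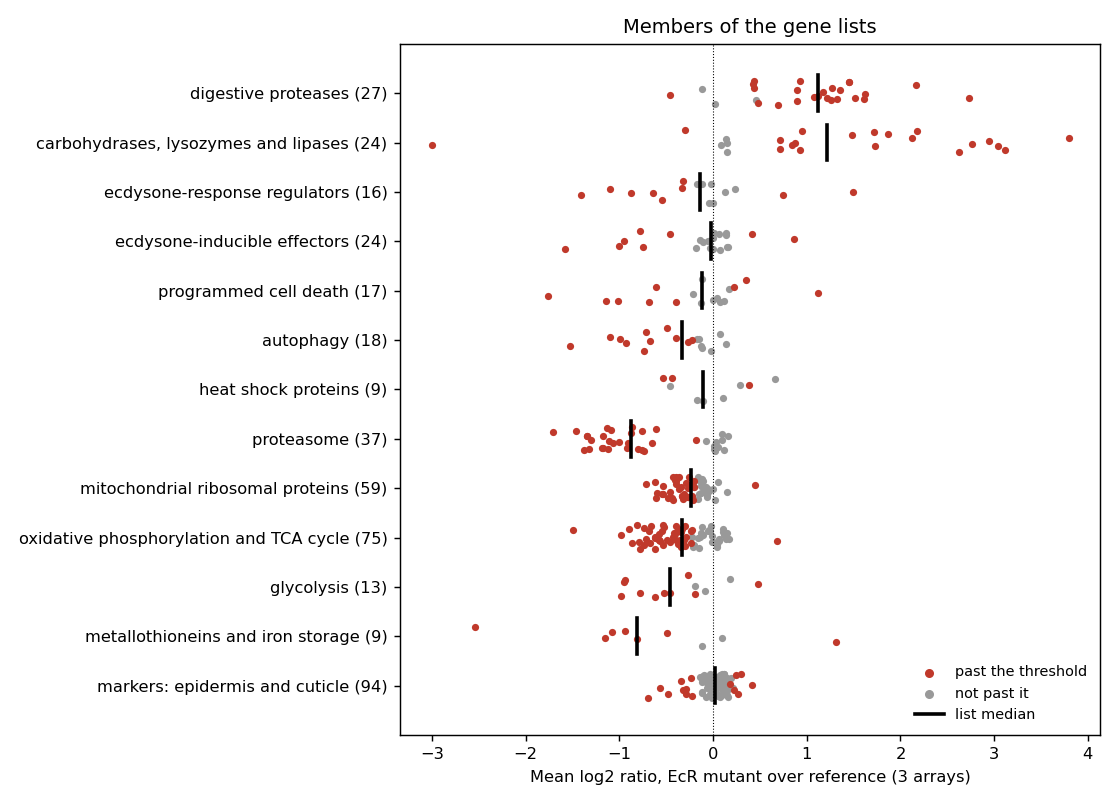
Each point is the mean log2 ratio over 3 arrays of 1 tested member of a gene list, red where it passed the threshold and grey where it did not, and the black bar is the list's median, with the number of members in brackets. The digestive protease and carbohydrase lists have medians of 1.12 and 1.22, the proteasome list has a median of -0.88, and the epidermis and cuticle markers gather near 0.

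Genes of the ecdysone response moved in both directions. The regulator list was written with 21 genes, but Eip74EF, Eip75B, Hr4, crol and Met were not among those tested. Of 16 regulators tested, 2 were higher, 7 were lower and 7 did not pass, with a median of -0.14, and the list as a whole did not pass (camera adjusted p = 0.224; adjusted p = 0.736 with an estimated correlation). Adjusted over the list alone, 3 were higher and 7 lower. The nuclear receptor gene Hr3 at -1.41 ± 0.33, Eip93F, a transcription factor of steroid-triggered cell death, at -1.10 ± 0.21 and vri at -0.87 ± 0.14 were lower. The further members that passed, named after their values were seen, were Hr78 at -0.64, ftz-f1 at -0.54, br at -0.33 and Hr39 at -0.32 on the lower side, and Hr96 at 0.75 beside EcR on the higher side. Without replicate 3, where EcR lost its call, 1 member was higher, and the median was -0.24 without replicate 4 and -0.050 without replicate 6. The values for usp, which encodes the partner of the receptor, and for Eip78C were -0.17 and -0.00065 and did not pass. Of 24 ecdysone-inducible effectors, 2 were higher, 6 were lower and 16 did not pass, both over all features and adjusted over the list alone, with a median of -0.022 (camera adjusted p = 0.666; adjusted p = 0.736 with an estimated correlation) that was -0.068 without replicate 3, -0.036 without replicate 6 and -0.0066 without replicate 4. When genes that more than 1 list holds were left out, 17 effectors remained, 1 higher and 3 lower, with a median of -0.0075. Cyp18a1, an enzyme that inactivates ecdysteroids, was lower at -1.58 ± 0.17, as were Fbp1 at -1.01 ± 0.31 and ImpE3 at -0.95 ± 0.39, and ImpL2, a secreted antagonist of insulin signalling, was higher at 0.87 ± 0.10.

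Cell death and autophagy genes included several with lower ratios. The cell death list was written with 22 genes, but rpr, hid, Drice, Decay and Diap1 were not among those tested. Of 17 genes of programmed cell death, 3 were higher, 6 were lower and 8 did not pass, with a median of -0.11 and no call for the list (camera adjusted p = 0.402; adjusted p = 0.736 with an estimated correlation). Adjusted over the list alone, 3 were higher and 7 lower. Dronc, the initiator caspase, was at -1.76 ± 0.26, crq, a receptor for apoptotic cells that is also in the hemocyte list, at -1.14 ± 0.15 and Buffy, a Bcl-2 family member, at -1.01 ± 0.23, while the caspase gene Damm was at 1.12 ± 0.33. Without genes that more than 1 list holds, 5 were lower and the median was -0.059, and over all members it was -0.073 without replicate 3 and -0.049 without replicate 6. Of 18 autophagy genes, 0 were higher, 11 were lower and 7 did not pass, with a median of -0.33 (camera adjusted p = 2.61e-04; adjusted p = 0.558 with an estimated correlation). Adjusted over the list alone, 12 were lower. Atg7 was at -1.53 ± 0.17, Atg5 at -1.10 ± 0.18, Atg18a at -1.0 ± 0.18 and Atg8b at -0.93 ± 0.13. Of 21 lysosomal genes, 5 were higher and 11 lower, both over all features and adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.153; fry adjusted p = 0.0246). Npc2a, a sterol-binding protein of the lysosome, was lower at -2.50 ± 0.10, Gal at -1.43 ± 0.07 and the cathepsin gene CtsL1 at -1.35 ± 0.52, and Npc2f was higher at 1.10 ± 0.22.

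**Figure D2:**
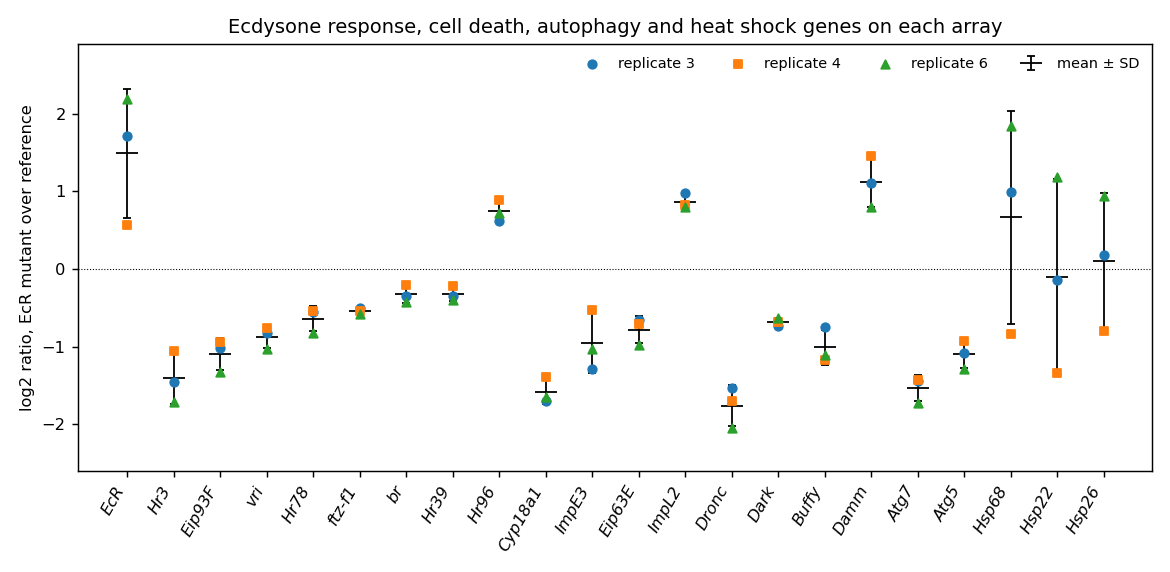
Log2 ratios of the EcR mutant over the reference are plotted for genes of the ecdysone response, cell death, autophagy and heat shock, with circles for replicate 3, squares for replicate 4, triangles for replicate 6 and a bar for the mean ± SD of the 3 arrays. EcR runs from 0.57 to 2.19, and Hsp68, Hsp22 and Hsp26 lie below 0 on replicate 4 and above 0 on replicate 6.

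The proteasome, which degrades ubiquitin-tagged proteins, had lower ratios in the mutant. Of its 37 members, 0 were higher, 27 were lower and 10 did not pass, with a median of -0.88 (camera adjusted p = 3.29e-09; adjusted p = 0.558 with an estimated correlation). Adjusted over the list alone, 1 was higher and 27 lower. Prosalpha6 was at -1.70 ± 0.11, Rpn12 at -1.46 ± 0.22, Rpt5 at -1.37 ± 0.13 and Rpn6 at -1.35 ± 0.13. Of 75 genes of oxidative phosphorylation and the TCA cycle, 1 was higher and 46 were lower (1 and 48 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 3.48e-07; adjusted p = 0.558 with an estimated correlation), among them Idh3b at -1.49 ± 0.51, COX4 at -0.98 ± 0.10, ATPsynG at -0.89 ± 0.10 and Scsalpha1 at -0.87 ± 0.02. Of 59 mitochondrial ribosomal proteins, 1 was higher and 36 were lower (1 and 39 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 4.57e-07; adjusted p = 0.487 with an estimated correlation), led by mRpL32 at -0.72 ± 0.13 and mRpS10 at -0.61 ± 0.07. Without replicate 3, 18 of these were lower. Of 13 glycolytic genes, 1 was higher and 9 were lower (1 and 10 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 0.00598; adjusted p = 0.558 with an estimated correlation), including Tpi at -0.99 ± 0.08 and Eno at -0.94 ± 0.12. Of 37 cytosolic ribosomal proteins, 6 were higher and 4 lower (6 and 2 adjusted over the list alone), with a median of 0.093 (camera adjusted p = 0.153). Its largest values were RpL24-like at 0.98 ± 0.15 and RpL10Ab at 0.86 ± 0.27, and without replicate 4 the list passed (adjusted p = 0.00401), with 10 higher and 2 lower. Over all 3 arrays its adjusted p = 0.804 with an estimated correlation. Without replicate 3, 6 were higher and 1 lower, and as deposited 9 were higher and 2 lower. The median was 0.15 without replicate 4 and 0.014 without replicate 6.

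Metal handling and detoxification genes formed mixed groups. Of 9 genes for metallothioneins and iron storage, 1 was higher and 6 were lower, both over all features and adjusted over the list alone, with a median of -0.81 (camera adjusted p = 0.0348; adjusted p = 0.558 with an estimated correlation). The copper transporter gene Ctr1B at -2.54 ± 0.08, MtnC at -1.16 ± 0.27 and Tsf2 at -1.08 ± 0.35 were lower, and Tsf1, a transferrin, was higher at 1.31 ± 0.07. This call was lost on receptor centring (adjusted p = 0.103), where the median was -0.91 and the counts were again 1 higher and 6 lower. Of 82 genes in the cytochrome P450 list, 26 were higher and 13 lower (26 and 14 adjusted over the list alone), with a median of 0.077 (camera adjusted p = 0.0308; adjusted p = 0.558 with an estimated correlation). Cyp4ac3 was at 2.52 ± 0.35, Cyp4ac1 at 1.78 ± 0.23 and Cyp6a9 at 1.64 ± 0.16. The list also took in Cyp1 and Cyp40, which are cyclophilins with similar symbols, and Cyp40 at -1.03 is counted among its lower members. On the values as deposited its adjusted p was 0.0611, and on receptor centring its median was -0.023, with 23 higher and 21 lower, while the set test, relative to the other genes, still passed as higher (adjusted p = 0.00426). Of 26 glutathione S-transferases, 10 were higher and 7 lower (12 and 7 adjusted over the list alone), with a median of 0.021 (camera adjusted p = 0.289). GstT4 was at 2.13 ± 0.17 and GstT3 at -1.52 ± 0.19. On receptor centring the median of the list turned to -0.078 (camera adjusted p = 0.0812, higher relative to the other genes). Without replicate 3, 6 were higher and 4 lower, and the median was 0.12 without replicate 4 and 0.012 without replicate 6. Of 12 antimicrobial peptides and recognition proteins, 0 were higher and 6 lower, both over all features and adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.0842; fry adjusted p = 0.0448), including PGRP-SC2 at -1.13 ± 0.32, PGRP-LA at -1.12 ± 0.31 and Def, a defensin, at -0.95 ± 0.39. That list passed with quantile normalization (adjusted p = 0.045) and, with a median of -0.15, without replicate 6 (adjusted p = 0.0491). Over all 3 arrays its adjusted p = 0.558 with an estimated correlation.

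Heat shock genes differed between the arrays. The list was written with 19 genes, but no Hsp70 gene, Hsp23 or Hsp83 was among those tested. Of 9 tested, 1 was higher, 2 were lower and 6 did not pass, both over all features and adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.811; adjusted p = 0.922 with an estimated correlation). Hsp60A, a mitochondrial chaperonin, was at -0.43 ± 0.08, CG4456 at -0.53 ± 0.44 and stv at 0.38 ± 0.25. The call of CG4456 was lost without replicate 3 or without replicate 4, and that of stv without replicate 3. Without replicate 4 the median of the list turned to 0.51, with 3 members higher and 1 lower. Hsp68, named after its values were seen, was at 0.99 on replicate 3, -0.84 on replicate 4 and 1.84 on replicate 6. The mutants had carried a heat shock inducible transgene, and EcR was lowest on the same array.

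**Figure D3:**
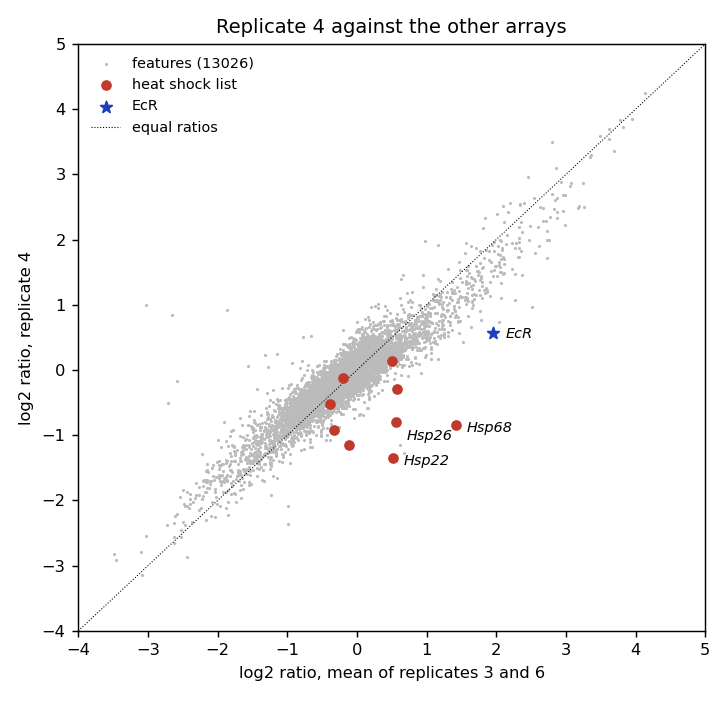
The log2 ratio of each of 13026 features on replicate 4 (vertical axis) is plotted against its mean on replicates 3 and 6 (horizontal axis), with the 9 heat shock genes in red, EcR as a star and equal ratios as a dotted line. Hsp68, Hsp22, Hsp26 and EcR lie below the line, and the slope over all features other than these genes and the rest of the heat shock list is 0.782.

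The remaining gut lists, 4 in number, did not pass the camera test. Among 16 genes of the peritrophic matrix and mucins, 3 were higher and 6 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.883), from Muc55B at 2.58 ± 0.16 to Mur89F at -1.60 ± 0.34, Gasp at -1.50 ± 0.62 and Peritrophin-15b at -1.23 ± 0.52. Its median of 0.013 and its mean of -0.23 differed in sign, and 7 were higher and 6 lower as deposited, 1 and 6 on receptor centring, and 1 and 5 without replicate 3. Among 23 vacuolar ATPase subunits, 3 were higher and 6 lower (4 and 7 adjusted over the list alone; camera adjusted p = 0.883), including Vha100-4 at 0.90 ± 0.16 and VhaM9.7-b at -0.74 ± 0.19, with a median of -0.027 that turned to 0.034 on the values as deposited, where 5 were higher and 4 lower. Without replicate 3, 2 subunits were higher and 3 lower. Among 21 cell cycle and replication genes, 0 were higher and 8 lower, both over all features and adjusted over the list alone (camera adjusted p = 0.224; fry adjusted p = 0.0448), led by PCNA at -1.29 ± 0.31 and RnrL at -0.52 ± 0.22, with a median of -0.053 that turned to 0.0074 on the values as deposited, where 1 was higher and 5 lower. The lower calls numbered 3 without replicate 3 and 4, with a median of -0.10, without replicate 6. Among 13 factors of gut identity and imaginal cells, 1 was higher and 3 lower, both over all features and adjusted over the list alone (camera adjusted p = 0.883). Egfr was at -0.60 ± 0.29, and the calls of spi at -0.45, esg at -0.39 and pnr at 0.43 were lost without replicate 3, which left 0 higher and 1 lower. The median of 0.012 and the mean of -0.07 of this list differed in sign.

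No list of tissue or cell type markers passed the camera test. By fry, which does not compare a list with other genes, the Malpighian tubule (lower, adjusted p = 0.0296), hemocyte (lower, adjusted p = 0.0342) and fat body (higher, adjusted p = 0.04997) lists passed. Of 9 fat body genes, 3 were higher and 3 lower (camera adjusted p = 0.733), with Fst at 2.41 ± 0.13 and Desat1 at 0.91 ± 0.30 against Fbp1 at -1.01 ± 0.31 and Lsp2 at -0.92 ± 0.34, and the median of -0.07 and mean of 0.13 differed in sign. When genes that more than 1 list holds were left out, 7 fat body genes remained, 3 higher and 1 lower. Of 12 hemocyte genes, 2 were higher and 4 lower (camera adjusted p = 0.248), with Sr-CI at -1.92 ± 0.50, crq at -1.14 ± 0.15 and Col4a1 at -0.67 ± 0.25. Of 94 epidermis and cuticle genes, 6 were higher and 9 lower with a median of 0.025 (camera adjusted p = 0.232), which turned to -0.075 on receptor centring. The balance of these calls turned with the scaling, with 20 higher and 7 lower as deposited and 1 and 15 on receptor centring, and 1 was higher and 1 lower without replicate 3 and 3 and 5 without replicate 6. Of 16 muscle genes, 3 were higher and 2 lower (camera adjusted p = 0.648), with bt at 0.58 ± 0.16. Of 7 Malpighian tubule genes, 0 were higher and 2 lower (camera adjusted p = 0.334), with ry at -1.56 ± 0.41. Of 10 nervous system genes, 1 was higher and 1 lower (camera adjusted p = 0.733), with nrv2 at -0.67 ± 0.24, and the median of 0.031 and mean of -0.023 differed in sign. Of 7 enteroendocrine hormone genes, 2 were higher and 1 lower (camera adjusted p = 0.351), with CCHa2 at 0.73 ± 0.24. Of 4 salivary gland genes, too few for a set test, 2 were higher and 0 lower. Adjusted over each list alone, the fat body list had 3 higher and 3 lower, the hemocyte list 2 and 6, the epidermis list 3 and 5, the muscle list 3 and 2, the Malpighian tubule list 0 and 2, the nervous system list 1 and 1, the enteroendocrine list 2 and 1, and the salivary gland list 3 and 0. Small counts here moved with the centring and with single arrays. As deposited the muscle list had 4 higher and 1 lower, the hemocyte list 2 and 3, the enteroendocrine list 3 and 1 and the salivary gland list 3 and 0. On receptor centring the muscle list had 2 and 3, the hemocyte list 0 and 6, the fat body list 2 and 3, the Malpighian tubule list 0 and 3, the nervous system list 0 and 1, the enteroendocrine list 1 and 1 and the salivary gland list 0 and 0. Without replicate 3, over all features, the muscle list had 1 higher and 0 lower, the hemocyte list 0 and 3, the Malpighian tubule list 0 and 1, the nervous system list 0 and 1, the enteroendocrine list 3 and 0 and the salivary gland list 0 and 0. Without replicate 4 the enteroendocrine list had 1 and 1 and the salivary gland list 1 and 0, and without replicate 6 the hemocyte list had 0 and 3, the muscle list 3 and 1, and the nervous system list 0 and 1 and the enteroendocrine list 1 and 1.

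Of the 28 lists with a set test, 9 passed with the preset correlation, 6 lower and 3 higher. With an estimated correlation 0 passed by camera and the smallest adjusted p was 0.487. That loss cannot be put down to correlation between genes alone. The adjusted p values given with an estimated correlation therefore do not measure the effect of correlation. The carbohydrase list had an estimated correlation of 0.0076, under the preset 0.01, yet its unadjusted camera p rose from 3.2e-10 to 0.0233. For the P450 list, at 0.0080, it rose from 0.00881 to 0.111. In the simulation this variant missed a list shifted by 1, so a call lost to it does not argue against a shift. At an unadjusted p under 0.05 the estimated correlation gave the carbohydrase list (p = 0.0233) and the mitochondrial ribosomal list (p = 0.0348). By fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, 17 passed.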

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

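Both centrings other than the planned ones, on probes with a value on all arrays and on receptor probes, were chosen only after the results were seen. No paired analysis was possible because the labels give only 1 group. Of the 121 named genes, 0 reversed under any alternative run. That follows largely from their choice: each had the same sign on all arrays, so leaving out 1 array could hardly turn it. The plain test, robust eBayes and the 1.5-fold bound leave the mean as it is. All 121 lost their call under the plain one-sample test. Without replicate 3, 20 lost it (EcR among them), without replicate 4 it was 4 and without replicate 6 it was 5. At a change of at least 1.5-fold 25 lost it, and on receptor centring 6. With robust eBayes 3 lost it, as deposited 1, and with each probe on its own 1. Signal over background is unknown for these arrays, so its limit on dim spots could not be assessed. The cause of the changes below was not tested, except that a stricter threshold and a minimum change lower counts by construction.

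The count of 4824 features became 4 with the plain test (1 higher, 3 lower), 3119 at an adjusted p under 0.01 (900 higher) and 1772 at 1.5-fold (535 higher, 1237 lower). The higher calls numbered 3038 on the values as deposited and 961 on receptor centring. Leaving out 1 replicate gave 2787 to 4628 in all, 792 to 1547 higher and 1995 to 3081 lower, with the lowest total and both lowest counts without replicate 3.

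With an estimated correlation the digestive protease list (median 1.12, adjusted p = 0.558) and the carbohydrase list (median 1.22, adjusted p = 0.487) lost their calls. By fry the ecdysone-inducible effectors (median -0.022, adjusted p = 0.0143) and programmed cell death (median -0.11, adjusted p = 0.0448) passed, as did the lysosomal (adjusted p = 0.0246), cell cycle (adjusted p = 0.0448) and antimicrobial (adjusted p = 0.0448) lists, which camera did not call. The effectors' median was 0.038 on the values as deposited. The heat shock median ran from -0.31 to 0.51 over the arrays left out, with 0.51 without replicate 4.

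With the plain test the members called numbered 0 in each direction in all 6 main lists. At 1.5-fold, 4 regulators were lower, 1 effector and 1 cell death gene higher, 0 proteases lower, 1 carbohydrase lower, and 0 heat shock genes higher and 0 lower. With each probe on its own, 11 regulator probes were lower, and 2 heat shock probes higher and 4 lower. As deposited, 4 effectors were higher. With robust eBayes 0 proteases and 1 heat shock gene were lower. On receptor centring 2 proteases were lower and 0 heat shock genes higher. Leaving out 1 replicate gave 1 to 3 regulators higher, 0 to 1 protease lower, and 0 to 3 heat shock genes higher and 1 to 4 lower.

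Further list medians that changed sign lay near 0. On receptor centring they were -0.087 for peritrophic matrix and mucins, -0.0063 for cytosolic ribosomal proteins, -0.023 for P450 enzymes, -0.078 for glutathione S-transferases, -0.088 for gut identity, -0.094 for muscle, -0.069 for nervous system and -0.075 for epidermis. As deposited they were 0.034 for the vacuolar ATPase and 0.0074 for the cell cycle. The peritrophic median was -0.039 with each probe on its own and also without shared genes, and the fat body median 0.12 without shared genes. The muscle median was -0.0020 after scaling and -0.0041 after quantile normalization. Over the arrays left out, the medians ran from -0.024 (without replicate 6) to 0.038 for the peritrophic list, from -0.054 to 0.0057 (without replicate 4) for the vacuolar ATPase, from -0.081 to 0.016 (without replicate 6) for fat body, and from -7.8e-05 (without replicate 3) to 0.067 for the nervous system, and the glutathione S-transferase median was -0.00058 without replicate 3.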

Other observations

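Further gene families had most called members on 1 side. Families were taken from the stems of gene symbols after the data were seen, 117 were tested, and each adjusted p below became 0.864 with an estimated correlation. Of 23 Vps genes, which act in vesicle sorting and of which Vps15 is also in the autophagy list, 0 were higher and 15 lower (median -0.25, camera adjusted p = 1.36e-04). Of 8 EMC genes, subunits of a membrane protein complex of the endoplasmic reticulum, 0 were higher and 7 lower (median -0.85, adjusted p = 0.0041). Of 11 Alp genes for alkaline phosphatases, 7 were higher and 0 lower (median 0.30, adjusted p = 0.00117), and of 29 Ugt genes for glucuronosyltransferases, 13 were higher and 5 lower (median 0.32, adjusted p = 0.0046).

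All tests below were chosen only after the result they concern was seen, except the count over sign patterns of the arrays. Replicate 4 stood apart in 2 opposite ways. On it Muc26B, a mucin gene, was at 0.92 against -1.32 on replicate 3 and -2.40 on replicate 6, Cda9, a chitin deacetylase gene, was at 0.23 against -1.33 and -1.31, and CG17826 was at 0.99 against -2.77 and -3.29. These 3 genes were chosen for their deviation.

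EcR and heat shock genes were low on replicate 4. Compressed ratios on that array keep their sign, which argues against them as the whole cause for the heat shock genes that turned. Of 5 with a mean of at least 0.5 on replicates 3 and 6, 4 lay below 0 on replicate 4. They did so by more than 0.198, the SD of the difference between replicates 3 and 6. Of all 686 features of that mean 6 did so, these 4 included. The genes had been seen to be low before this count. That SD is taken over all features and may understate their spread, as Hsp22 was at -0.14 on replicate 3 and 1.18 on replicate 6. For EcR compression stays open. Its value on replicate 4 was 0.293 of its mean on replicates 3 and 6. The slope over the other features was 0.7817 (bootstrap SE 0.0066), which met the bound set against compression. That bound, however, left out the scatter of single genes. EcR had been named in advance, but it was compared on replicate 4 because it had been seen to be low there. Whether a heat shock response differed between the samples also stays open: the median deviation of the 9 heat shock genes on replicate 4 was -0.8699, below all 10000 random lists of that size (central range -0.12 to 0.16), and EcR ranked 6 of 13026 from the bottom, but these genes had been seen to be low before the test, so the values restate the pattern. The rescue transgene is heat shock inducible, and the files do not say whether the EcR probe also detects its RNA.

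Small changes were common in both directions, and 1237 of the 3081 lower calls reached 1.5-fold. Among the 1743 higher calls 535 did, so many features called higher had small ratios. A zero level set too low by the array median may account for part of this, since 86.67% of 105 chemosensory receptor genes, known mainly from sensory neurons, lay above 0 (91 genes; exact 95% interval 78.6% to 92.5%; median 0.09). These genes are not known to be unchanged, as 14 of them were called higher and 5 lower. Their signal over background is unknown, so they may not show where 0 lies for expressed genes. Whether the small calls are real rises stays open. Of 1208 higher calls under 1.5-fold, 430 (35.6%) were also made on receptor centring. That met the bound of 50% set for arguing against real rises, but the bound was wrong: this centring takes the same amount from every gene of an array, so a call lost to it does not exclude a rise. Of the 535 higher calls of at least 1.5-fold, 531 were made on that centring too.

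Digestive enzyme genes were higher and proteasome and autophagy genes lower. A dye effect and the mixture of stages in the reference cannot be told apart from the genotype, because 0 arrays had the mutant in Cy3 (dye effect without a dye swap) and 0 arrays held wild-type midgut at a single stage (stages mixed in the reference). The transgene of the mutants and any difference in heat shock or strain background cannot be told apart from the genotype either. The loss of EcR function, the difference that the design names, stays among the open explanations and was not tested separately from them.

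Whether the proteasome paralogs fell along with the main subunits stays open. The 12 paralogs named with T or R had a median of 0.03, with 2 lower calls, and the 25 other members, which were lower without exception, had a median of -1.11 (difference 1.1389). The split was made after these values had been seen, and signal over background is unknown, so paralogs near 0 may not have been measurable.

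Neighbouring genes often changed in the same direction, although examples had been seen before this was tested. Of 75 pairs of adjacent protein-coding genes that both passed and changed at least 2-fold, 60 (80.0%) had the same sign, against 36.6% to 69.7% in 1000 shuffled orders, where the highest number of such pairs was 53. Runs included Mal-A3, Mal-A4 and Mal-A5 at 2.12, 1.72 and 2.63, and CG14204, CG14219 and CG14205 at 3.59, 3.78 and 3.65. Cross-hybridisation between similar neighbouring copies was not tested.

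The 3 arrays allow 4 sign patterns, too few for a share under 0.05. The arrays as they are gave 4824 features past the threshold by limma, and the highest of the other patterns gave 0, with 1 pattern, the real one, reaching that count.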
